A study of Homo sapiens with 12 samples.

How the data were processed

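Total RNA of 12 xenograft tumours was measured on an Affymetrix whole-transcript human gene array, 3 tumours for each of the 4 groups. Per the labels' protocols, HT29 cells stably expressing the empty vector or a CK1δ mutant were injected under the skin of athymic mice, the tumours were removed after 27 days, RNA was isolated from frozen tissue with a column kit, and biotin-labelled sense target was hybridised. The deposited values are log2 signals, 1 per transcript cluster and array. Per the processing notes the authors made them with Affymetrix Expression Console. Its version, summarisation, background step, normalization between arrays and genome build are not given in the sources used here. The array files are not used here. The array distributions were close and not identical, so no further scaling was applied. Their SD was 2.29 to 2.34 in ctrl, 2.35 in T67S and I68N and 2.32 to 2.33 in P66T/R69K.

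The table holds 33297 rows. Of the 21214 rows with a gene annotation, 19460 have exactly 1 symbol and 1754 have several. The other 12083 rows have no annotation. The row with the highest mean was kept for each of 18417 genes, 769 of which had more than 1 row, and no filter on dim genes was applied. Of the rows with 1 symbol, 19429 were found in a reference gene table of assembly GRCh38.p14 by gene ID, and 0 symbols needed updating. That table was used for names and for the order of neighbouring genes only. Of 857 entries in 38 gene lists, 781 were measured, with older symbols matched through the table's synonyms only where they were not current symbols. This last condition was set after the values were seen, to undo 2 wrong matches, and changed no list call.

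Differences were tested with limma 3.58.1 (R 4.3.3 with the package data.table, version 1.17.8), with lmFit and eBayes on the 12 arrays in 1 fit of the 4 group means. This left 8 residual and 3.73 prior degrees of freedom. There were 7 contrasts: each mutant against ctrl, each pair of mutants, and the mean of the mutants against ctrl. An F test covered the 4 groups. Tests were 2-sided, p was adjusted by Benjamini-Hochberg over all genes of a comparison, and an adjusted p under 0.05 was called. Errors of differences are standard errors of the fit, and errors of levels are SD. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. CSNK1D was also tested with an exact 2-sided permutation of 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

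The groups, comparisons, lists, alternatives and rule for naming genes were chosen before the data were examined. The CK1 family is named first. In each comparison with ctrl follow the 10 genes that rose and the 10 that fell most among those called whose 3 and 3 arrays do not overlap, without uncharacterised loci and small RNA genes. Between mutants and for the mean the rule takes 5 and 5, and for the F test the 10 smallest p. Up to 4 members with the smallest p come from each called list, and up to 2 from each of 4 lists chosen for the known roles of the kinase. Of the list members so named, mainly those that passed whichever array was left out are printed, a choice made after the values were seen.

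The alternatives were quantile normalization, leaving out the 33.3% dimmest genes, testing all rows with 1 symbol, a fit of only the 2 groups compared, a robust variance trend, the replicate number as a block, a correlation estimated per list, and leaving out each array. Where this left a group with 2 arrays, the pooled spread of the fit was used. Array weights per group were added after seeing the data, because ctrl was more spread than the mutants. Shared calls were compared with 100 simulations of unchanged groups against shared controls. They may miss shifts that a ctrl array shares across genes. For stretches of neighbours, the median log2 fold change over 50 genes in order, of 9203 expressed genes, was compared with the highest of 100 shuffled orders, and a stretch beyond it is called shifted.

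The procedure was tested on simulated data with the T67S against ctrl comparison of 18417 genes, where 50 genes were changed by each size. It recovered 80% of genes changed by 0.5 in log2, 94% at 1, 100% at 2 and 92% at -1, with 4.69% false among 192 calls. An unchanged I68N against ctrl comparison of the 18417 genes gave 0 calls in limma. These simulated groups shared 1 spread per gene, whereas the real ctrl arrays were more spread than the mutants. The rates may therefore not hold for the comparisons with ctrl. The simulations of shared calls, drawn with each group's own spread, did give calls without any change (below). A list shifted by 0.3 in I68N was found, with 1 other of 38 lists called.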

Results

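Tumours grown from HT29 cells, a human colon carcinoma line, were profiled on whole-transcript arrays. The cells carried an empty vector (ctrl) or 1 of 3 stably expressed mutants of casein kinase 1δ (CK1δ), a serine/threonine kinase with roles in the circadian clock, Wnt signalling and cell division, altered in exon 3: T67S, I68N or the double mutant P66T/R69K. Each of the 4 groups holds 3 tumours taken 27 days after injection under the skin of athymic nude mice. The 12 arrays, few for precision, are named by group and replicate (ctrl 1). Array medians ranged from 6.8 to 6.95 on the log2 scale. Pairs of arrays correlated across rows at 0.985 to 0.998 within groups and 0.986 to 0.994 between groups. The ctrl tumours were the most spread, with a pooled SD per gene of 0.206, against 0.119 in T67S, 0.0972 in I68N and 0.11 in P66T/R69K. Mean correlation was lowest for ctrl 2 with its own group (0.988) and for ctrl 1, of highest median, with other groups (0.989). Their pair was lowest within groups. Gene p-values measure the spread between tumours, pooled over the groups, and list p-values rest on the preset correlation between genes. Each group may be 1 stable line, since the labels do not say whether it is a clone or a pool or whether each tumour came from its own mouse. The genes named first are the largest changes that passed and whose 3 and 3 arrays did not overlap, as in 10% of unchanged genes.

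CSNK1D, the gene of CK1δ, was at a similar signal in the 4 groups: 11.20 ± 0.04 in ctrl, 11.13 ± 0.03 in T67S, 11.18 ± 0.01 in I68N and 11.27 ± 0.04 in P66T/R69K (log2, SD, n = 3). Against ctrl the difference was -0.06 for T67S (95% confidence interval -0.17 to 0.04), -0.02 for I68N (-0.13 to 0.09) and 0.07 for P66T/R69K (-0.04 to 0.18). None passed: limma's adjusted p was 0.456, 0.838 and 0.492, and an exact two-sided permutation test gave p = 0.2, 0.4 and 0.2, where 3 arrays against 3 cannot go below 0.1. The gene ranked at percentile 95.8 of all genes by mean signal. The labels do not say which part of the gene the constructs carry or whether the probes read it, so this leaves the expression of the mutants open. Among the other family members, CSNK1G2 had the widest differences, 0.23 ± 0.12 in T67S (adjusted p = 0.237), 0.23 ± 0.12 in I68N (adjusted p = 0.275) and 0.17 ± 0.12 in P66T/R69K (adjusted p = 0.496). CSNK1A1, CSNK1A1L and CSNK1G1 did not pass against ctrl either, the difference farthest from 0 being -0.15 ± 0.07 for CSNK1A1L in I68N (adjusted p = 0.27). CSNK1E is not analysed here because its row is annotated to 2 symbols, and CSNK1G3 has no row with a single symbol.

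**Figure D1:**
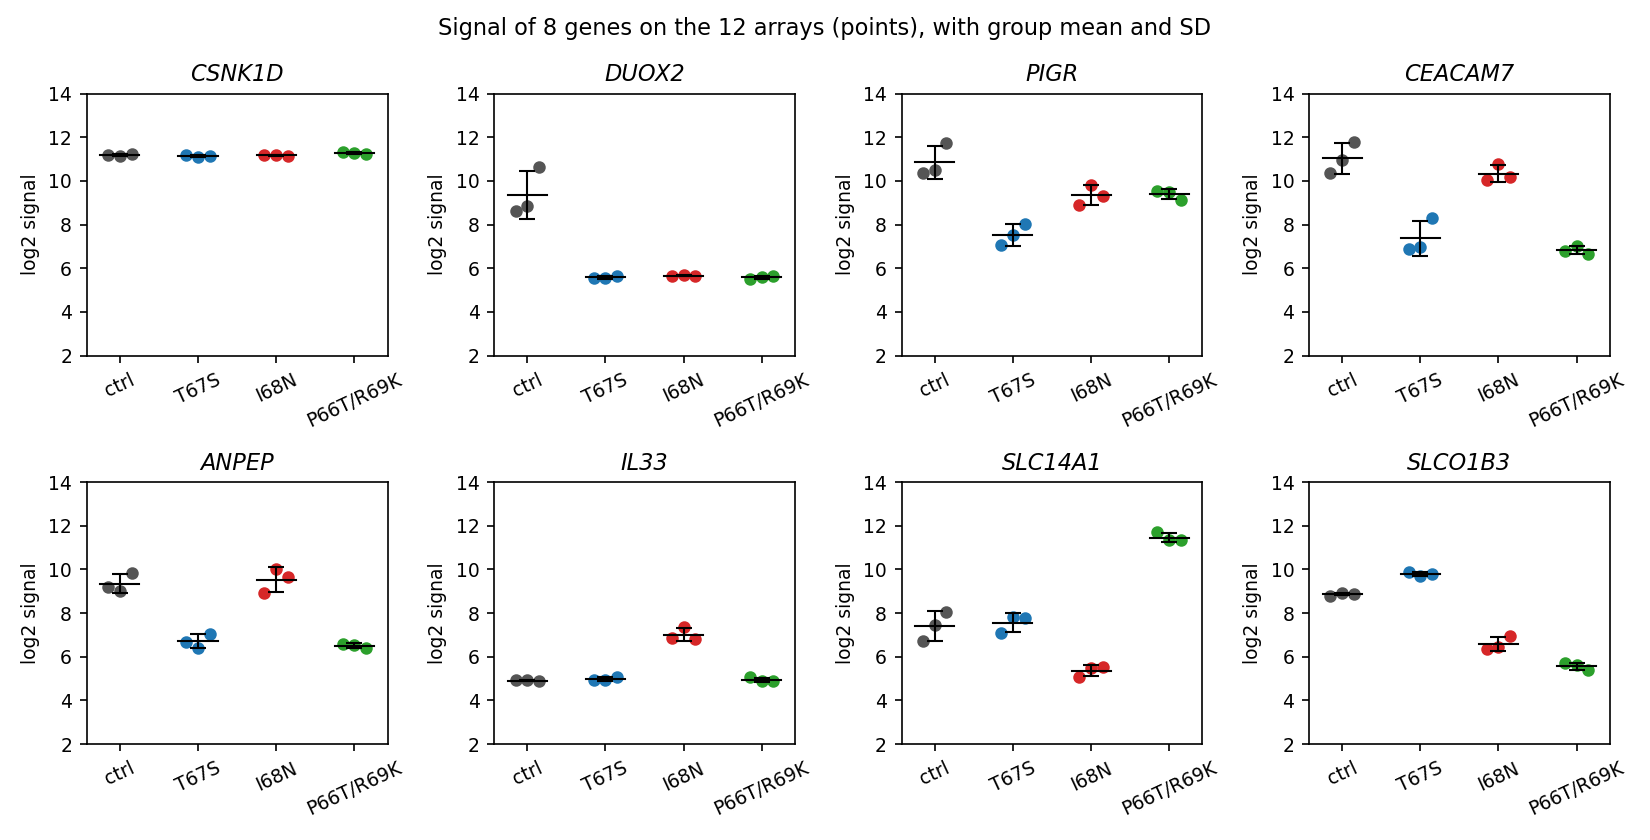
Log2 signal (y axis) of CSNK1D and 7 genes with large differences on the 12 arrays (points) by group (x axis), with bars for the group mean and SD. DUOX2 is lower in all 3 mutant groups than in ctrl, and SLC14A1 spans 5.37 ± 0.26 in I68N to 11.46 ± 0.21 in P66T/R69K.

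The first comparison asks which transcripts differ in tumours of the T67S mutant. DUOX2, the dual oxidase that makes hydrogen peroxide at mucosal surfaces, was the gene that dropped most, and it fell by 3.78 ± 0.38 (adjusted p = 0.000761), in log2 units with the standard error (n = 3 per group, here and below). Its maturation factor DUOXA2 fell too (-1.95 ± 0.33, adjusted p = 0.00785). CEACAM7, an adhesion molecule of the carcinoembryonic antigen family (-3.65 ± 0.39, adjusted p = 0.000937), PIGR, which carries immunoglobulin A across epithelia (-3.34 ± 0.35, adjusted p = 0.000937), and ANPEP, the aminopeptidase N of the brush border (-2.62 ± 0.27, adjusted p = 0.000919), were lower by several-fold. The other genes among the 10 largest falls were the pantetheinases VNN2 (-2.51 ± 0.41, adjusted p = 0.00679) and VNN1 (-2.01 ± 0.27, adjusted p = 0.00325), AUTS2 (-1.92 ± 0.11, adjusted p = 1.68e-05), the growth factor TGFB2 (-1.80 ± 0.35, adjusted p = 0.0143) and the membrane mucin MUC17 (-1.79 ± 0.43, adjusted p = 0.0346). LYN, a Src-family tyrosine kinase, led the rises (1.65 ± 0.22, adjusted p = 0.00323), followed by ENPP2, the autotaxin that makes lysophosphatidic acid (1.44 ± 0.35, adjusted p = 0.0372), and the cationic amino acid transporter SLC7A2 (1.29 ± 0.19, adjusted p = 0.0046). Further rises were those of CEP15 (1.25 ± 0.11, adjusted p = 0.000546), the protease inhibitor SERPINE2 (1.24 ± 0.18, adjusted p = 0.00408), the enoyl-CoA isomerase ECI2 (1.24 ± 0.18, adjusted p = 0.00408) and the cohesin acetyltransferase ESCO2 (1.23 ± 0.31, adjusted p = 0.0422). ZDHHC2, a palmitoyltransferase (1.20 ± 0.13, adjusted p = 0.000937), ELAPOR1 (1.19 ± 0.30, adjusted p = 0.0426) and the ileal bile acid binding protein FABP6 (1.18 ± 0.12, adjusted p = 0.000681) completed them. Leaving out 1 array ended the calls for TGFB2 (ctrl 3, adjusted p = 0.0575 or T67S 1, 0.0583), MUC17 (any array but ctrl 2, P66T/R69K 1 or P66T/R69K 2, 0.0504 to 0.128), ENPP2 (any array but ctrl 1, ctrl 2, I68N 2 or P66T/R69K 1, 0.0542 to 0.12), ESCO2 (any array but ctrl 2 or P66T/R69K 1, 0.0577 to 0.142) and ELAPOR1 (any array but ctrl 1 or ctrl 2, 0.0565 to 0.14). Quantile normalization ended the call for ELAPOR1 (adjusted p = 0.0589). Array weights per group ended the calls for MUC17 (adjusted p = 0.103), ENPP2 (0.066) and ELAPOR1 (0.0808). A robust variance trend ended the calls for ESCO2 (adjusted p = 0.0513) and ELAPOR1 (0.0515). In the fit of the 6 arrays alone, 5 of these 20 genes passed: CEP15, ZDHHC2, FABP6, ANPEP and AUTS2. LYN, ESCO2 and ZDHHC2 lie in stretches of neighbouring genes shifted together (shifted stretches below).

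Gene lists fixed beforehand gave 13 calls of 38 in T67S against ctrl, with medians of the log2 fold change. Of all list calls here only those of NF-kB genes in T67S and in the mean of the mutants passed with an estimated correlation. Interferon response genes fell as a list (29 members, median -0.50, adjusted p = 2.6e-09, or 0.647 with an estimated correlation). Of these, 4 fell (14 adjusted over the list alone) and 25 did not pass. All 29 estimates were negative. Genes of MHC class I antigen presentation fell as a list (10 members, median -0.56, adjusted p = 1.79e-07, or 0.629 with it estimated). Among them 5 fell (7 over the list alone) and 5 did not pass. They included the immunoproteasome subunit PSMB10 (-0.37 ± 0.06, adjusted p = 0.00527). NF-kB and inflammatory genes fell as a list (23 members, median -0.28, adjusted p = 2.45e-08, or 0.0278 with it estimated). Individually, 9 fell (1 rose and 14 fell over the list alone) and 14 did not pass. Among the falls were TNFAIP2 (-1.43 ± 0.17, adjusted p = 0.00181) and NFKBIZ (-0.81 ± 0.11, adjusted p = 0.00342), both induced by NF-kB. Enterocyte differentiation genes fell as a list (25 members, median -0.10, adjusted p = 0.0318, or 0.647 with it estimated). Of these, 2 rose and 3 fell (4 rose and 5 fell over the list alone) and 20 did not pass. Slightly lower were the markers of endothelium (22 members, median -0.08, adjusted p = 0.0318, individually 1 lower, over the list alone 1 lower), with adjusted p = 0.629 with it estimated. List calls ended without 1 array for enterocyte genes (ctrl 1, adjusted p = 0.146 or T67S 2, 0.0774) and endothelium (ctrl 1, 0.088 or ctrl 2, 0.0577). In kept calls medians moved over 1.5 times to -0.33 for interferon response without ctrl 2 and -0.12 for endothelium without T67S 3. Calls were also lost for endothelium (adjusted p = 0.221) after quantile normalization. The 2-group fit ended the calls for PSMB10 (adjusted p = 0.0987), TNFAIP2 (0.0751) and NFKBIZ (0.0655).

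Bright lists of growth and metabolism (percentile 74.1 to 98.9) rose in T67S. Array SD was higher too, so scale may contribute. DNA replication and G1/S genes rose as a list (29 members, median 0.31, adjusted p = 4.93e-06, or 0.669 with an estimated correlation). Of these, 1 rose (2 adjusted over the list alone) and 28 did not pass. Genes of mitosis and G2/M rose as a list (31 members, median 0.28, adjusted p = 4.93e-06, or 0.669 with it estimated). None of them passed individually in limma (14 with an unadjusted p under 0.05, none over the list alone). Cytosolic ribosomal protein genes rose as a list (30 members, median 0.18, adjusted p = 5.71e-06, or 0.629 with it estimated). Among them 3 rose (14 over the list alone) and 27 did not pass. Ribosome biogenesis and MYC target genes rose as a list (25 members, median 0.24, adjusted p = 6.06e-06, or 0.629 with it estimated). Individually, 2 rose (4 over the list alone) and 23 did not pass. The nucleolar methyltransferase FBL rose (0.46 ± 0.08, adjusted p = 0.00858, or 0.0907 in the 2-group fit). Oxidative phosphorylation genes rose as a list (29 members, median 0.19, adjusted p = 1.01e-06, or 0.629 with it estimated). Of these, 5 rose (10 over the list alone) and 24 did not pass. Calls for higher values were also made for histones (30 members, median 0.21, adjusted p = 0.00111, individually 2 higher, over the list alone 3 higher), heat shock response (10 members, median 0.17, adjusted p = 0.0158, individually 1 higher, over the list alone 2 higher) and cholesterol biosynthesis (19 members, median 0.18, adjusted p = 0.0318, individually 2 higher, over the list alone 2 higher), with adjusted p = 0.629 to 0.669 with it estimated. List calls ended without 1 array for ribosomal proteins (ctrl 2, adjusted p = 0.135), histones (T67S 2, 0.107), heat shock response (ctrl 1, 0.0626) and cholesterol biosynthesis (ctrl 1, 0.243 or T67S 1, 0.126). In kept calls medians moved over 1.5 times to 0.45 for mitosis, 0.35 for histones and 0.29 for cholesterol biosynthesis without ctrl 2. Heat shock response and cholesterol biosynthesis were lost after quantile normalization (adjusted p = 0.234 and 0.274) and without the dimmest genes (0.14 and 0.15).

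Outside these lists, the Wnt targets NKD1 (-0.49 ± 0.09, adjusted p = 0.012) and LGR5 (0.98 ± 0.22, adjusted p = 0.0299) and the p53 target CCNG1 (0.53 ± 0.10, adjusted p = 0.0116) changed in T67S, while the p53 target RRM2B (0.78 ± 0.21, adjusted p = 0.0554), in a shifted stretch, and the clock genes BHLHE41 (-0.42 ± 0.14, adjusted p = 0.0998) and NR1D1 (-0.30 ± 0.12, adjusted p = 0.165) did not pass. Leaving out 1 array ended the calls for NKD1 (T67S 1, adjusted p = 0.0584), LGR5 (ctrl 3, 0.117, T67S 1, 0.0719 or I68N 1, 0.0514) and CCNG1 (ctrl 3, 0.0566 or T67S 1, 0.0543). Array weights per group ended the calls for NKD1, LGR5 and CCNG1 (adjusted p = 0.0533, 0.0987 and 0.0551). The 2-group fit did so too (0.0876, 0.2 and 0.0656). In all, 982 of 18417 genes passed, 716 higher and 266 lower, 232 of them by at least 1.5-fold. The share higher was 72.9%, but 58.3% of 849 after quantile normalization and 56.5% of 851 without ctrl 1. The count was 11 in a fit of the 6 arrays of these groups alone and 360 with array weights per group, chosen after seeing the data. It was 272 without T67S 1, 283 without ctrl 3, 435 without T67S 2, 588 without I68N 1 and 4752 without ctrl 2.

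In the I68N tumours IL33, an alarmin cytokine, rose most against ctrl (2.10 ± 0.12, adjusted p = 7.93e-06), and MTSS1, which shapes membranes and actin (2.05 ± 0.25, adjusted p = 0.000986), CXCR4, the receptor of CXCL12 (1.99 ± 0.34, adjusted p = 0.00744), and the prolactin receptor PRLR (1.97 ± 0.16, adjusted p = 8.47e-05) rose by a like amount. DUOX2 (-3.70 ± 0.38, adjusted p = 0.000371) and DUOXA2 (-1.88 ± 0.33, adjusted p = 0.00868) fell here as well. SLCO1B3, a transporter of organic anions (-2.26 ± 0.14, adjusted p = 7.96e-06), MUC5B, a gel-forming mucin (-2.09 ± 0.38, adjusted p = 0.0106), and the urea transporter SLC14A1 (-2.04 ± 0.30, adjusted p = 0.00309) were the next largest falls. The mucus protein FCGBP (-1.94 ± 0.44, adjusted p = 0.0289), the calcium-activated chloride channel ANO1 (-1.89 ± 0.23, adjusted p = 0.00092), the membrane skeleton protein EPB41L2 (-1.72 ± 0.24, adjusted p = 0.00278), the protease inhibitor SLPI (-1.68 ± 0.38, adjusted p = 0.0284) and the neutrophil chemokine CXCL1 (-1.57 ± 0.24, adjusted p = 0.00405) fell too. Rises were also found for MS4A8 (1.83 ± 0.34, adjusted p = 0.012), the GABA-A receptor subunit GABRA2 (1.76 ± 0.22, adjusted p = 0.00126) and the drug-metabolising cytochrome CYP2B6 (1.75 ± 0.17, adjusted p = 0.000267). The selenium carrier SELENOP (1.74 ± 0.27, adjusted p = 0.00472), TMEM176A (1.73 ± 0.30, adjusted p = 0.00887) and the brush border protease MEP1A (1.73 ± 0.23, adjusted p = 0.00174) followed. Leaving out 1 array ended the calls for FCGBP (any of ctrl 1, ctrl 3, I68N 1, I68N 2 or I68N 3, adjusted p = 0.0704 to 0.117), SLPI (any of ctrl 3, I68N 1, I68N 2 or I68N 3, 0.0825 to 0.0963) and MS4A8 (I68N 2, 0.0608). Array weights per group ended the call for SLPI (adjusted p = 0.0674). The 2-group fit kept 13 of these 20 genes. Those lost were CXCR4 (adjusted p = 0.0527), DUOXA2 (0.106), MUC5B (0.111), FCGBP (0.163), SLPI (0.0594), CXCL1 (0.0719) and MS4A8 (0.0794). MTSS1 lies in a shifted stretch.

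Of 38 gene lists, 9 were called in I68N against ctrl. NF-kB and inflammatory genes fell as a list (23 members, median -0.26, adjusted p = 4.8e-06, or 0.0669 with an estimated correlation). Of these, 5 fell (10 adjusted over the list alone) and 18 did not pass. CXCL1 was one of these. Interferon response genes fell as a list (29 members, median -0.31, adjusted p = 4.8e-06, or 0.869 with it estimated). Among them 1 fell (the same over the list alone) and 28 did not pass. Genes of MHC class I antigen presentation fell as a list (10 members, median -0.25, adjusted p = 0.0333, or 0.869 with it estimated). Individually, 1 fell (3 over the list alone) and 9 did not pass. YAP/TEAD target genes fell as a list (20 members, median -0.15, adjusted p = 0.0141, or 0.869 with it estimated). Of these, 2 fell (the same over the list alone) and 18 did not pass. The guanine nucleotide exchange factor DOCK5 (-0.69 ± 0.07, adjusted p = 0.000313), also in a shifted stretch, was 1 of these. Xenobiotic metabolism and NRF2 target genes rose as a list (26 members, median 0.16, adjusted p = 0.0141, or 0.869 with it estimated). Among them 4 rose (8 over the list alone) and 22 did not pass. The glutathione transferase GSTA4 (0.95 ± 0.11, adjusted p = 0.000665) rose. The p53 target genes rose as a list (22 members, median 0.15, adjusted p = 0.0487, or 0.869 with it estimated). Individually, 4 rose (4 rose and 1 fell over the list alone) and 18 did not pass. The sestrin SESN1 (1.04 ± 0.12, adjusted p = 0.000867) was the clearest of them. Cytosolic ribosomal protein genes rose as a list (30 members, median 0.12, adjusted p = 0.00309, or 0.869 with it estimated). Of these, 4 rose (8 over the list alone) and 26 did not pass. Higher too were oxidative phosphorylation (29 members, median 0.11, adjusted p = 0.00974, individually 2 higher, over the list alone 3 higher) and glycolysis (16 members, median 0.15, adjusted p = 0.0358, individually 1 higher, over the list alone 1 higher), with adjusted p = 0.869 with it estimated. Without 1 array list calls ended for MHC class I (ctrl 2, adjusted p = 0.337, ctrl 3, 0.0695 or I68N 3, 0.269), YAP/TEAD targets (ctrl 2, 0.165), p53 targets (any array but ctrl 2, T67S 1, I68N 1, P66T/R69K 1 or P66T/R69K 2, 0.0506 to 0.159), ribosomal proteins (ctrl 2, 0.645) and glycolysis (any of ctrl 1, ctrl 2, I68N 2 or I68N 3, 0.0502 to 0.345). Medians of kept calls moved over 1.5 times to 0.05 for xenobiotic metabolism without ctrl 1, -0.09 for interferon response, 0.23 for p53 targets and 0.18 for oxidative phosphorylation without ctrl 2 and -0.14 for interferon response without I68N 3. Calls for p53 targets, glycolysis and oxidative phosphorylation were also lost after quantile normalization (adjusted p = 0.0734, 0.242 and 0.251). The same held without the dimmest genes (0.238, 0.131 and 0.07).

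PROX1, a transcription factor on the Wnt target list, rose in I68N (1.13 ± 0.16, adjusted p = 0.00297). CD44 (0.23 ± 0.06, adjusted p = 0.054), the clock genes BMAL1 (0.36 ± 0.12, adjusted p = 0.112) and CRY1 (0.35 ± 0.12, adjusted p = 0.133) and the mitosis genes CKAP2 (0.32 ± 0.13, adjusted p = 0.18), in a shifted stretch, and PRC1 (-0.23 ± 0.10, adjusted p = 0.185) did not pass. In all, 915 of 18417 genes passed, 668 higher and 247 lower, 260 of them by at least 1.5-fold. The share higher was 73%, but 63.6% of 855 after quantile normalization and 63.4% of 756 without ctrl 1. The count was 191 in the 2-group fit and 473 with array weights per group. It was 267 without I68N 2, 327 without I68N 1, 490 without I68N 3, 573 without ctrl 3 and 4184 without ctrl 2.

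The double mutant P66T/R69K had the largest single differences from ctrl. CLEC3A, a C-type lectin first known from cartilage (4.26 ± 0.27, adjusted p = 1.24e-05), and the urea transporter SLC14A1 (4.05 ± 0.30, adjusted p = 4.58e-05) rose, and CEACAM7 (-4.20 ± 0.39, adjusted p = 0.000312), DUOX2 (-3.78 ± 0.38, adjusted p = 0.000396) and SLCO1B3 (-3.29 ± 0.14, adjusted p = 3.56e-07) fell. Lower too were ANPEP (-2.84 ± 0.27, adjusted p = 0.000332), the liver-intestine cadherin CDH17 (-2.61 ± 0.40, adjusted p = 0.00445), the annexin ANXA13 (-2.54 ± 0.28, adjusted p = 0.000738) and the carcinoembryonic antigen CEACAM5 (-2.45 ± 0.25, adjusted p = 0.00045). The protease inhibitors PI3 (-2.42 ± 0.33, adjusted p = 0.00252) and SLPI (-2.11 ± 0.38, adjusted p = 0.0103) and the galectin LGALS2 (-2.07 ± 0.37, adjusted p = 0.0105) fell as well. Other rises were those of the succinate receptor SUCNR1 (2.32 ± 0.42, adjusted p = 0.0109), JCAD (2.02 ± 0.15, adjusted p = 4.97e-05) and ZMAT1 (1.95 ± 0.08, adjusted p = 3.56e-07) and the ubiquitin ligase RNF157 (1.91 ± 0.13, adjusted p = 3.6e-05). The interferon-induced chemokine CXCL10 (1.69 ± 0.34, adjusted p = 0.0194), the MHC class II peptide loading protein HLA-DMB (1.61 ± 0.26, adjusted p = 0.00658), the guanosine monophosphate reductase GMPR (1.60 ± 0.14, adjusted p = 0.00014) and the interferon-induced TRIM22 (1.47 ± 0.36, adjusted p = 0.0444) completed the 10 largest. Leaving out 1 array ended the calls for CXCL10 (any of ctrl 3, P66T/R69K 1, P66T/R69K 2 or P66T/R69K 3, adjusted p = 0.0593 to 0.0764) and TRIM22 (any array but ctrl 2 or I68N 3, 0.0557 to 0.133). Array weights and a robust variance trend ended the call for TRIM22 (adjusted p = 0.12 and 0.0553). Fitting 2 groups alone ended the calls for SUCNR1 (adjusted p = 0.119), CXCL10 (0.137) and TRIM22 (0.137). CEACAM5, CEACAM7 and ANPEP lie in shifted stretches.

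In this comparison 14 of 38 lists were called. Interferon response genes rose as a list (29 members, median 0.74, adjusted p = 5.49e-17, or 0.408 with an estimated correlation). Of these, 7 rose (28 adjusted over the list alone) and 22 did not pass. All 29 estimates were positive, and the ubiquitin-like protein ISG15 (0.72 ± 0.09, adjusted p = 0.00122) rose. Genes of MHC class I antigen presentation rose as a list (10 members, median 0.32, adjusted p = 0.000526, or 0.436 with it estimated). Among them 1 rose (6 over the list alone) and 9 did not pass. Enterocyte differentiation genes fell as a list (25 members, median -0.13, adjusted p = 1.5e-05, or 0.301 with it estimated). Individually, 6 fell (7 over the list alone) and 19 did not pass. CEACAM6, in a shifted stretch, was among them (-1.61 ± 0.25, adjusted p = 0.00476). Goblet and secretory lineage genes fell as a list (25 members, median -0.28, adjusted p = 0.000555, or 0.408 with it estimated). Of these, 3 fell (6 over the list alone) and 22 did not pass. Hypoxia response genes fell as a list (24 members, median -0.43, adjusted p = 2.4e-08, or 0.412 with it estimated). None of them passed individually in limma (15 with an unadjusted p under 0.05, 12 fell over the list alone). The prolyl hydroxylase P4HA1 (-0.80 ± 0.21, adjusted p = 0.0553) and the stress-induced inhibitor of growth signalling DDIT4 (-1.23 ± 0.34, adjusted p = 0.0703) are examples. Glycolysis genes fell as a list (16 members, median -0.22, adjusted p = 6.86e-05, or 0.436 with it estimated). Among them 3 fell (7 over the list alone) and 13 did not pass. The isomerase GPI (-0.49 ± 0.07, adjusted p = 0.00354) and the pyruvate kinase PKM (-0.36 ± 0.06, adjusted p = 0.0067), the latter in a shifted stretch, fell. NF-kB and inflammatory genes fell as a list (23 members, median -0.15, adjusted p = 1.5e-05, or 0.122 with it estimated). Individually, 2 fell (10 over the list alone) and 21 did not pass. The mitochondrial superoxide dismutase SOD2 (-0.58 ± 0.06, adjusted p = 0.00073), again from a shifted stretch, fell. In kept calls medians moved over 1.5 times to -0.07 for enterocyte genes and -0.05 for goblet genes without ctrl 1, -0.20 for enterocyte genes and -0.46 for goblet genes without ctrl 2 and -0.17 for goblet genes and -0.29 for hypoxia response without ctrl 3. Fitting 2 groups alone ended the calls for CEACAM6 (adjusted p = 0.0556), GPI (0.0548) and PKM (0.0677).

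Further lists were lower in P66T/R69K. Immediate early genes fell as a list (24 members, median -0.18, adjusted p = 0.000325, or 0.338 with an estimated correlation). Of these, 1 fell (the same adjusted over the list alone) and 23 did not pass. Cytosolic ribosomal protein genes fell as a list (30 members, median -0.13, adjusted p = 1.33e-05, or 0.412 with it estimated). None of them passed individually in limma (12 with an unadjusted p under 0.05, 2 fell over the list alone). Xenobiotic metabolism and NRF2 target genes fell as a list (26 members, median -0.09, adjusted p = 0.0236, or 0.436 with it estimated). Among them 2 fell (1 rose and 3 fell over the list alone) and 24 did not pass. The cytochrome CYP2S1 (-1.06 ± 0.11, adjusted p = 0.000396), in a shifted stretch, and the aldo-keto reductase AKR1B10 (-1.25 ± 0.20, adjusted p = 0.00488) fell. Of the marker lists of other cell types, lower were those of keratinocytes (16 members, median -0.15, adjusted p = 0.000166, individually 1 lower, over the list alone 6 lower), muscle (20 members, median -0.14, adjusted p = 0.000526, individually none by limma, 4 unadjusted, over the list alone none) and adipocytes (15 members, median -0.09, adjusted p = 0.0182, individually none by limma, 4 unadjusted, over the list alone none), with adjusted p = 0.142 to 0.436 with it estimated. In contrast, genes of DNA replication and the G1/S transition rose as a list (29 members, median 0.15, adjusted p = 0.00406, or 0.863 with it estimated). None of them passed individually in limma (1 unadjusted, none over the list alone). List calls ended without 1 array for xenobiotic metabolism (ctrl 2, adjusted p = 0.22, ctrl 3, 0.0668 or P66T/R69K 2, 0.0953), adipocytes (ctrl 1, 0.0801 or P66T/R69K 2, 0.0746) and DNA replication (ctrl 1, 0.345 or ctrl 3, 0.0709). In kept calls medians moved over 1.5 times to -0.15 for adipocytes and 0.30 for DNA replication without ctrl 2. Calls were also lost for adipocytes (adjusted p = 0.0506) after quantile normalization, and for xenobiotic metabolism (adjusted p = 0.25) without the dimmest genes. Fitting 2 groups alone ended the call for AKR1B10 (adjusted p = 0.067).

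The Wnt targets LEF1, a transcription factor of the pathway, and ZNRF3, a ubiquitin ligase that removes its receptors, rose (0.91 ± 0.11, adjusted p = 0.00141, and 0.42 ± 0.07, adjusted p = 0.00825), as did the clock gene PER3 (0.72 ± 0.12, adjusted p = 0.00672) and the p53 target FAS (0.57 ± 0.14, adjusted p = 0.0499). The clock gene BHLHE40 (-0.84 ± 0.21, adjusted p = 0.046) fell, as did the p53 target TNFRSF10B (-0.45 ± 0.10, adjusted p = 0.0349) and the mitosis gene PRC1 (-0.40 ± 0.10, adjusted p = 0.0394), both in shifted stretches like the mitotic cyclin CCNB2 (-0.32 ± 0.11, adjusted p = 0.142), which did not pass. Leaving out 1 array ended the calls for FAS (any array but ctrl 2, adjusted p = 0.0556 to 0.178), BHLHE40 (any array but ctrl 2, T67S 2 or T67S 3, 0.0572 to 0.15), TNFRSF10B (any array but ctrl 2, T67S 2, T67S 3, I68N 2 or I68N 3, 0.0546 to 0.127) and PRC1 (any array but ctrl 2, ctrl 3, T67S 3 or I68N 3, 0.0534 to 0.144). Array weights ended the calls for FAS (adjusted p = 0.0971), BHLHE40 (0.181), TNFRSF10B (0.162) and PRC1 (0.136). Testing all rows ended the call for FAS (adjusted p = 0.051). Fitting 2 groups alone ended the calls for ZNRF3 (adjusted p = 0.0555), PER3 (0.0799), FAS (0.219), TNFRSF10B (0.0515) and PRC1 (0.157). In all, 759 of 18417 genes passed, 450 higher and 309 lower, 242 of them by at least 1.5-fold. The share higher was 59.3%, but 50.4% of 633 without ctrl 1 and 68% of 2673 without ctrl 2. The count was 150 in the 2-group fit and 316 with array weights per group. It was 332 without P66T/R69K 3, 334 without P66T/R69K 2, 341 without P66T/R69K 1, 467 without ctrl 3, 491 without I68N 1 and 2673 without ctrl 2.

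**Figure D2:**
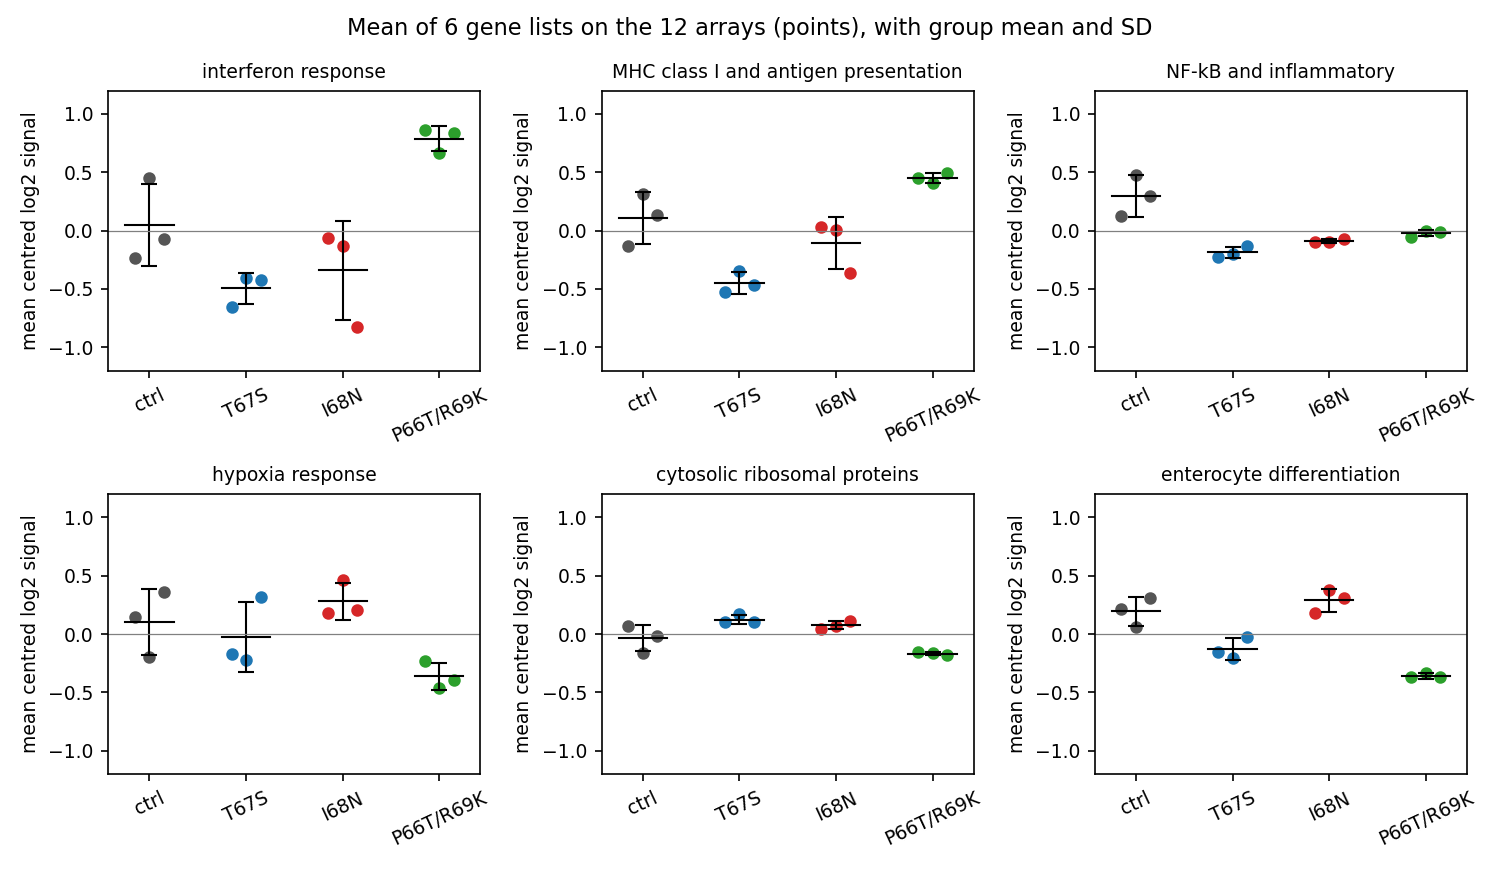
Mean of the centred log2 signal over the members of 6 gene lists (y axis) on the 12 arrays (points) by group (x axis), with bars for the group mean and SD. The interferon response mean was 0.79 ± 0.11 in P66T/R69K, 0.05 ± 0.35 in ctrl, -0.34 ± 0.42 in I68N and -0.50 ± 0.14 in T67S.

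Set against each other, the single mutants differed most in SLCO1B3, which was higher in T67S than in I68N (3.20 ± 0.14, adjusted p = 2.38e-07), and in CEACAM7, which was lower (-2.95 ± 0.39, adjusted p = 0.000788). Higher in T67S were also EPB41L2 (2.46 ± 0.24, adjusted p = 0.000116), SLC7A2 (2.39 ± 0.19, adjusted p = 2.58e-05), ANO1 (2.37 ± 0.23, adjusted p = 8.26e-05) and SLC14A1 (2.20 ± 0.30, adjusted p = 0.000963). Lower in T67S were ANPEP (-2.81 ± 0.27, adjusted p = 8.83e-05), AUTS2 (-2.57 ± 0.11, adjusted p = 2.38e-07), MTSS1 (-2.42 ± 0.25, adjusted p = 0.000136) and GABRA2 (-2.39 ± 0.22, adjusted p = 7.12e-05). All 10 held without any 1 array, in the 2-group fit and with array weights. SLC14A1 and the lower CEACAM7 lie in stretches higher in T67S.

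Of the lists, 11 differed between T67S and I68N. Genes of DNA replication and the G1/S transition were higher in T67S as a list (29 members, median 0.34, adjusted p = 1.55e-09, or 0.765 with an estimated correlation). Of these, 2 were higher (11 adjusted over the list alone) and 27 did not pass. The helicase subunit MCM4 (0.81 ± 0.15, adjusted p = 0.00613), in a shifted stretch, was 1 of them. Genes of mitosis and G2/M were higher in T67S as a list (31 members, median 0.34, adjusted p = 1.55e-09, or 0.765 with it estimated). Among them 1 was higher (none over the list alone) and 30 did not pass. Replication-dependent histone genes were higher in T67S as a list (30 members, median 0.27, adjusted p = 5.09e-08, or 0.765 with it estimated). Individually, 3 were higher (9 over the list alone) and 27 did not pass. Ribosome biogenesis and MYC target genes were higher in T67S as a list (25 members, median 0.15, adjusted p = 0.000385, or 0.765 with it estimated). Of these, 1 was higher (the same over the list alone) and 24 did not pass. This was FBL (0.45 ± 0.08, adjusted p = 0.00509), also in a shifted stretch. Enterocyte differentiation genes were lower in T67S as a list (25 members, median -0.11, adjusted p = 0.000305, or 0.765 with it estimated). Among them 1 was higher and 8 were lower (2 higher and 9 lower over the list alone) and 16 did not pass. Sucrase-isomaltase, SI (-2.22 ± 0.38, adjusted p = 0.00429), and the carbonic anhydrase CA2 (-0.77 ± 0.13, adjusted p = 0.00471) were lower in T67S. Further calls were oxidative phosphorylation (29 members, median 0.07, adjusted p = 0.034, individually 1 higher, over the list alone 1 higher), MHC class I (10 members, median -0.32, adjusted p = 0.000305, individually 1 lower, over the list alone 1 lower), xenobiotic metabolism (26 members, median -0.07, adjusted p = 0.0477, individually 1 higher and 1 lower, over the list alone 1 higher and 3 lower) and endothelium (22 members, median -0.04, adjusted p = 0.034, individually 3 lower, over the list alone 4 lower), with adjusted p = 0.765 to 0.791 with it estimated. Hypoxia response genes were lower in T67S as a list (24 members, median -0.27, adjusted p = 0.0026, or 0.791 with it estimated). Individually, 2 were lower (1 higher and 2 lower over the list alone) and 22 did not pass. These were the carbonic anhydrase CA12 (-1.06 ± 0.14, adjusted p = 0.000883) and the prolyl hydroxylase P4HA2 (-1.07 ± 0.15, adjusted p = 0.00145). Circadian clock genes were lower in T67S as a list (19 members, median -0.12, adjusted p = 0.0451, or 0.765 with it estimated). Of these, 2 were lower (5 over the list alone) and 17 did not pass. Among the falls was the repressor BHLHE41 (-0.73 ± 0.14, adjusted p = 0.00845). Without 1 array list calls ended for oxidative phosphorylation (any of T67S 1, T67S 2, I68N 1 or I68N 3, adjusted p = 0.0537 to 0.0919), xenobiotic metabolism (any array but ctrl 1, ctrl 3, T67S 1, I68N 3 or P66T/R69K 2, 0.0517 to 0.188), endothelium (T67S 1, 0.064 or I68N 3, 0.0605) and circadian clock (any of ctrl 1, ctrl 2, T67S 1, T67S 2, I68N 1 or I68N 2, 0.052 to 0.165). Medians of kept calls moved over 1.5 times to 0.18 for histones and 0.10 for ribosome biogenesis without T67S 2, 0.23 for ribosome biogenesis, -0.19 for enterocyte genes, -0.08 for endothelium and -0.53 for hypoxia response without T67S 3, -0.22 for enterocyte genes without I68N 1 and -0.07 for enterocyte genes and -0.11 for xenobiotic metabolism without I68N 3. After quantile normalization calls were lost for circadian clock, oxidative phosphorylation, xenobiotic metabolism and endothelium (adjusted p = 0.0588 each). Without the dimmest genes they were lost for oxidative phosphorylation (0.132) and xenobiotic metabolism (0.133). In all, 1008 of 18417 genes passed, 513 higher and 495 lower, 410 of them by at least 1.5-fold. The count was 1785 in the 2-group fit and 1991 with array weights per group. It was 573 without I68N 2, 595 without I68N 1, 604 without T67S 1, 645 without T67S 2 and 1722 without ctrl 2.

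Between T67S and P66T/R69K, SLCO1B3 was higher in T67S (4.23 ± 0.14, adjusted p = 2.81e-08) and CLEC3A lower (-4.76 ± 0.27, adjusted p = 2.79e-06). The adhesion molecule CDH17 (3.25 ± 0.40, adjusted p = 0.0003), ANXA13 (2.51 ± 0.28, adjusted p = 0.000175), the ferric reductase CYBRD1 (2.43 ± 0.17, adjusted p = 7.77e-06) and SERPINE2 (2.31 ± 0.18, adjusted p = 1.65e-05) were higher in T67S. SLC14A1, SUCNR1 and the interferon-induced CXCL10 and TRIM22 were lower (-3.89 ± 0.30, adjusted p = 1.59e-05, -2.50 ± 0.42, adjusted p = 0.00215, -2.94 ± 0.34, adjusted p = 0.00021 and -2.73 ± 0.36, adjusted p = 0.000439, in this order). The 10 calls held in the 2-group fit, with array weights and whichever array was left out. CDH17 and ANXA13 lie in shifted stretches.

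Among the lists, 12 were called, and 2 of these were lower in T67S. Interferon response genes were lower in T67S as a list (29 members, median -1.25, adjusted p = 1.59e-23, or 0.54 with an estimated correlation). Of these, 28 were lower (the same adjusted over the list alone) and 1 did not pass. The interferon-induced genes IFI44 (-1.95 ± 0.23, adjusted p = 0.000192) and RSAD2 (-2.15 ± 0.28, adjusted p = 0.000392) were lower in T67S. Antigen presentation genes of MHC class I were lower in T67S as a list (10 members, median -0.80, adjusted p = 1.07e-09, or 0.481 with it estimated). Among them 7 were lower (10 over the list alone) and 3 did not pass. The peptide transporter subunit TAP2 (-1.38 ± 0.13, adjusted p = 6.56e-05) is an example. Cytosolic ribosomal protein genes were higher in T67S as a list (30 members, median 0.33, adjusted p = 1.81e-11, or 0.481 with it estimated). Individually, 17 were higher (24 over the list alone) and 13 did not pass. An example is RPS2 (0.35 ± 0.05, adjusted p = 0.00118). Genes of mitosis and G2/M were higher in T67S as a list (31 members, median 0.34, adjusted p = 7.43e-06, or 0.641 with it estimated). Of these, 6 were higher (the same over the list alone) and 25 did not pass. The spindle protein PRC1 (0.54 ± 0.10, adjusted p = 0.00306) and the cyclin CCNB2 (0.56 ± 0.11, adjusted p = 0.00533) were higher in T67S, the latter in a shifted stretch. Glycolysis genes were higher in T67S as a list (16 members, median 0.30, adjusted p = 1.42e-05, or 0.621 with it estimated). Among them 7 were higher (11 over the list alone) and 9 did not pass. GPI (0.70 ± 0.07, adjusted p = 9.93e-05), in a shifted stretch, was higher in T67S. Oxidative phosphorylation genes were higher in T67S as a list (29 members, median 0.22, adjusted p = 1.42e-05, or 0.621 with it estimated). Individually, 11 were higher (13 over the list alone) and 18 did not pass. Cytochrome c1, CYC1 (0.58 ± 0.10, adjusted p = 0.0018), was higher in T67S. Further calls were ribosome biogenesis (25 members, median 0.22, adjusted p = 0.00013, individually 5 higher, over the list alone 9 higher), cholesterol biosynthesis (19 members, median 0.29, adjusted p = 0.00119, individually 3 higher, over the list alone 10 higher and 1 lower), histones (30 members, median 0.23, adjusted p = 0.00272, individually 4 higher, over the list alone 4 higher) and xenobiotic metabolism (26 members, median 0.11, adjusted p = 0.0411, individually 7 higher, over the list alone 8 higher), with adjusted p = 0.621 to 0.673 with it estimated. CYP2S1, a cytochrome in a shifted stretch, was higher in T67S (1.85 ± 0.11, adjusted p = 2.79e-06). Hypoxia response genes were higher in T67S as a list (24 members, median 0.33, adjusted p = 0.00927, or 0.673 with it estimated). Of these, 3 were higher (the same over the list alone) and 21 did not pass. Epithelial junction genes were higher in T67S as a list (21 members, median 0.09, adjusted p = 0.0411, or 0.673 with it estimated). Among them 5 were higher (7 higher and 1 lower over the list alone) and 16 did not pass. List calls ended without 1 array for histones (T67S 2, adjusted p = 0.0874), xenobiotic metabolism (any of ctrl 2, T67S 1, T67S 3 or P66T/R69K 2, 0.0505 to 0.0866), hypoxia response (T67S 3, 0.137) and epithelial junctions (any of T67S 1, T67S 3, P66T/R69K 1 or P66T/R69K 2, 0.0521 to 0.129). Epithelial junctions were lost after quantile normalization (adjusted p = 0.489, median -0.02). Without the dimmest genes, calls for epithelial junctions and xenobiotic metabolism were lost (0.102 and 0.156), as with the replicate block (0.0519 each). In all, 2677 of 18417 genes passed, 1465 higher and 1212 lower, 772 of them by at least 1.5-fold. The count was 3842 in the 2-group fit and 4034 with array weights per group. It was 1626 without P66T/R69K 2, 1670 without P66T/R69K 3, 1700 without T67S 1 and 4238 without ctrl 2.

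Between I68N and P66T/R69K the widest difference was that of SLC14A1, lower in I68N (-6.09 ± 0.30, adjusted p = 5.57e-07). CLEC3A (-4.46 ± 0.27, adjusted p = 2.99e-06), CXCL10 (-2.86 ± 0.34, adjusted p = 0.000378), HLA-DMB (-2.37 ± 0.26, adjusted p = 0.000242) and the interferon-induced SAMD9L (-2.20 ± 0.33, adjusted p = 0.00153) were lower in I68N too. CEACAM7 (3.51 ± 0.39, adjusted p = 0.000237), CDH17 (3.17 ± 0.40, adjusted p = 0.00054), ANPEP (3.03 ± 0.27, adjusted p = 5.88e-05), sucrase-isomaltase SI (2.53 ± 0.38, adjusted p = 0.00142) and CXCR4 (2.40 ± 0.34, adjusted p = 0.000989) were higher. Leaving out any single array, the 2-group fit and array weights ended none of these 10 calls. CDH17 and ANPEP lie in shifted stretches.

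For this pair 11 lists were called. Interferon response genes were lower in I68N as a list (29 members, median -1.10, adjusted p = 3.73e-23, or 0.394 with an estimated correlation). Of these, 25 were lower (29 adjusted over the list alone) and 4 did not pass. IFIT1 was lower in I68N (-1.96 ± 0.26, adjusted p = 0.000692). Antigen presentation genes of MHC class I were lower in I68N as a list (10 members, median -0.63, adjusted p = 1.36e-05, or 0.394 with it estimated). Among them 6 were lower (7 over the list alone) and 4 did not pass. The regulator of these genes NLRC5 (-0.81 ± 0.14, adjusted p = 0.00313) was lower in I68N. Hypoxia response genes were higher in I68N as a list (24 members, median 0.70, adjusted p = 2.37e-07, or 0.528 with it estimated). Individually, 12 were higher (17 over the list alone) and 12 did not pass. CA12, in a shifted stretch, and P4HA1 were higher in I68N (1.22 ± 0.14, adjusted p = 0.000303, and 1.36 ± 0.21, adjusted p = 0.0017). Glycolysis genes were higher in I68N as a list (16 members, median 0.31, adjusted p = 5.44e-08, or 0.394 with it estimated). Of these, 9 were higher (13 over the list alone) and 7 did not pass. The lactate dehydrogenase LDHA (0.41 ± 0.07, adjusted p = 0.00252) and the pyruvate dehydrogenase kinase PDK1 (1.31 ± 0.27, adjusted p = 0.00907) were higher in I68N. Enterocyte differentiation genes were higher in I68N as a list (25 members, median 0.31, adjusted p = 1.82e-06, or 0.394 with it estimated). Among them 10 were higher (14 over the list alone) and 15 did not pass. The peptidase DPP4 (0.85 ± 0.10, adjusted p = 0.000325) and CEACAM5 (2.15 ± 0.25, adjusted p = 0.000332) were among them. Cytosolic ribosomal protein genes were higher in I68N as a list (30 members, median 0.25, adjusted p = 4.13e-10, or 0.394 with it estimated). Individually, 16 were higher (the same over the list alone) and 14 did not pass. RPS2 was higher in I68N (0.34 ± 0.05, adjusted p = 0.00219). Xenobiotic metabolism and NRF2 target genes were higher in I68N as a list (26 members, median 0.23, adjusted p = 3.56e-05, or 0.394 with it estimated). Of these, 10 were higher and 1 was lower (the same over the list alone) and 15 did not pass. The efflux pump ABCG2 (0.92 ± 0.13, adjusted p = 0.00134) and GSTA4 (1.14 ± 0.11, adjusted p = 8.2e-05) were higher in I68N. Further calls were oxidative phosphorylation (29 members, median 0.13, adjusted p = 0.00421, individually 6 higher, over the list alone 7 higher), DNA replication (29 members, median -0.21, adjusted p = 0.00117, individually 1 lower, over the list alone none) and muscle (20 members, median 0.10, adjusted p = 0.0437, individually none by limma, 2 with an unadjusted p under 0.05, over the list alone none), with adjusted p = 0.612 to 0.76 with it estimated. YAP/TEAD target genes were lower in I68N as a list (20 members, median -0.11, adjusted p = 0.0217, or 0.528 with it estimated). Among them 3 were lower (5 over the list alone) and 17 did not pass. DOCK5 was lower in I68N (-0.72 ± 0.07, adjusted p = 8.5e-05). List calls ended without 1 array for muscle (ctrl 2, adjusted p = 0.0502, I68N 3, 0.557 or P66T/R69K 1, 0.122). In kept calls medians moved over 1.5 times to -0.13 for DNA replication without P66T/R69K 1. List calls lost were those for oxidative phosphorylation (adjusted p = 0.0534) after quantile normalization, and for muscle (adjusted p = 0.205) without the dimmest genes. In all, 2039 of 18417 genes passed, 1161 higher and 878 lower, 579 of them by at least 1.5-fold. The count was 3961 in the 2-group fit and 3933 with array weights per group. It was 1032 without P66T/R69K 3, 1061 without I68N 2, 1140 without P66T/R69K 2, 1154 without I68N 1, 1322 without I68N 3 and 3375 without ctrl 2.

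**Figure D3:**
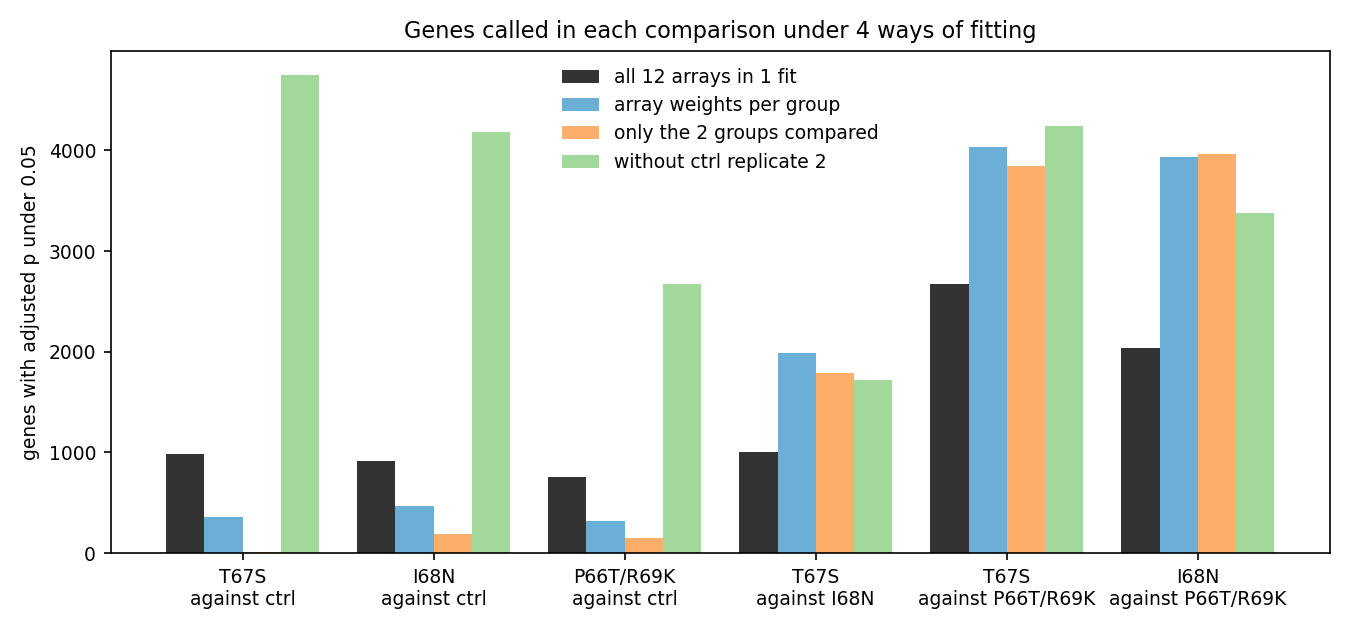
Genes with an adjusted p under 0.05 (y axis, number of genes) in the 6 comparisons of groups (x axis), as bars for 4 ways of fitting. Against ctrl the count is lower with array weights or in the 2-group fit (the bar of 11 genes for T67S is hardly visible) and higher without ctrl 2, while between mutants all 3 alternatives give more genes.

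The mean of the 3 mutant groups was also set against ctrl. This contrast can be carried by 1 or 2 mutants, so a call does not show a change common to all 3. DUOX2 (-3.75 ± 0.31, adjusted p = 0.000312), PIGR (-2.11 ± 0.29, adjusted p = 0.00627), MUC5B (-1.93 ± 0.31, adjusted p = 0.0129), DUOXA2 (-1.92 ± 0.27, adjusted p = 0.00704) and the cystatin CST1 (-1.42 ± 0.26, adjusted p = 0.0242) fell, and FABP6 (1.10 ± 0.09, adjusted p = 0.000354), CEP15 (1.06 ± 0.09, adjusted p = 0.000418), RNF157 (1.05 ± 0.11, adjusted p = 0.00159) and PLEKHS1 (0.99 ± 0.13, adjusted p = 0.00559) and MPP7 (0.89 ± 0.16, adjusted p = 0.0208) rose. Leaving out 1 array ended the calls for MUC5B (ctrl 3, adjusted p = 0.0624), CST1 (any of ctrl 3, T67S 1, I68N 1, I68N 2 or I68N 3, 0.0511 to 0.106) and MPP7 (ctrl 1, 0.0539 or I68N 1, 0.0513). Array weights per group ended the calls for PLEKHS1 (adjusted p = 0.0793) and MPP7 (0.162). In all, 246 of 18417 genes passed, 178 higher and 68 lower, 54 of them by at least 1.5-fold. The share higher was 72.4%, but 63.8% of 260 after quantile normalization, 53.3% of 30 with array weights and 51.8% of 247 without ctrl 1. The count was 30 with array weights per group. It was 72 without ctrl 3, 98 without I68N 1, 110 without I68N 2, 130 without T67S 1, 138 without I68N 3, 138 without P66T/R69K 2, 145 without P66T/R69K 1, 153 without T67S 2, 154 without P66T/R69K 3 and 4099 without ctrl 2.

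For the mean, 11 of 38 lists were called. NF-kB and inflammatory genes fell as a list (23 members, median -0.26, adjusted p = 2.53e-11, or 0.00913 with an estimated correlation). Of these, 4 fell (14 adjusted over the list alone) and 19 did not pass. Enterocyte differentiation genes fell as a list (25 members, median -0.06, adjusted p = 0.0231, or 0.695 with it estimated). Among them 2 rose and 4 fell (3 rose and 6 fell over the list alone) and 19 did not pass. CEACAM7 fell (-2.85 ± 0.32, adjusted p = 0.00221). Also lower were keratinocytes (16 members, median -0.07, adjusted p = 0.0125, individually 1 lower, over the list alone 1 lower), goblet genes (25 members, median -0.09, adjusted p = 0.0243, individually 2 lower, over the list alone 3 lower), hypoxia response (24 members, median -0.12, adjusted p = 0.0125, individually none by limma, 1 with an unadjusted p under 0.05, over the list alone none), immediate early genes (24 members, median -0.12, adjusted p = 0.0231, individually 1 higher, over the list alone 2 higher and 1 lower), MHC class I (10 members, median -0.16, adjusted p = 0.0308, individually none by limma, 2 unadjusted, over the list alone none) and muscle (20 members, median -0.07, adjusted p = 0.0308, individually none by limma, 1 unadjusted, over the list alone none), with adjusted p = 0.49 to 0.695 with it estimated. Higher lists were oxidative phosphorylation (29 members, median 0.10, adjusted p = 0.00321, individually none by limma, 8 unadjusted, over the list alone 2 higher), DNA replication (29 members, median 0.14, adjusted p = 0.0125, individually none by limma, 2 unadjusted, over the list alone none) and ribosome biogenesis (25 members, median 0.13, adjusted p = 0.0231, individually none by limma, 4 unadjusted, over the list alone none), with adjusted p = 0.695 to 0.713 with it estimated. List calls ended without 1 array for enterocyte genes (ctrl 1, adjusted p = 0.095 or ctrl 3, 0.12), goblet genes (ctrl 1, 0.249 or ctrl 3, 0.178), hypoxia response (ctrl 3, 0.462), immediate early genes (ctrl 3, 0.147), MHC class I (any of ctrl 2, ctrl 3, T67S 3, I68N 3 or P66T/R69K 2, 0.0558 to 0.521), muscle (any of ctrl 2, T67S 3, I68N 1 or I68N 2, 0.0558 to 0.428), DNA replication (ctrl 1, 0.539 or ctrl 3, 0.17) and ribosome biogenesis (ctrl 3, 0.315 or T67S 2, 0.0596). In kept calls medians moved over 1.5 times to -0.08 for immediate early genes and 0.07 for oxidative phosphorylation without ctrl 1 and -0.11 for enterocyte genes, -0.16 for goblet genes, -0.25 for hypoxia response and 0.28 for DNA replication without ctrl 2. Calls were also lost for DNA replication (adjusted p = 0.0706), enterocyte genes (0.0706), goblet genes (0.0716), oxidative phosphorylation (0.114), ribosome biogenesis (0.29), muscle (0.29) and keratinocytes (0.104) after quantile normalization, and for DNA replication (adjusted p = 0.0559), ribosome biogenesis (0.101) and muscle (0.0559) without the dimmest genes. The Wnt target list was not called against ctrl in any mutant. Its medians were -0.02, 0.06 and 0.05 in T67S, I68N and P66T/R69K (adjusted p = 0.434, 0.457 and 0.0741).

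Calls against ctrl were compared between the mutants. T67S and I68N had 188 genes higher in both and 56 lower in both (26 and 3.57 in independent lists), and 39 in opposite directions. T67S and P66T/R69K had 59 and 35 (17.5 and 4.46), and 89 in opposite directions. I68N and P66T/R69K had 87 and 52 (16.3 and 4.14), and 39 in opposite directions. In the simulations of unchanged groups, shared calls averaged 23.2, 25.3 and 22.9 in this order of pairs. Across genes, which are not independent replicates, the fold changes correlated at 0.491, 0.158 and 0.246, against 0.782, 0.764 and 0.797 in the simulations, and the covariance differed from the simulated one by 0.0102, -0.00637 and -0.00231. All 3 mutants shared 35 genes higher (simulated mean 9.74, highest 21) and 20 lower (9.89, highest 24), where independent lists would share 0.635 and 0.0599. Of the 31 higher genes placed in order, 12 lie in shifted stretches from ZMYND11 to JMJD1C (1.09% of the order). Part of the excess of higher genes may be regional. The genes lower in all 3 included DUOX2 (-3.78 in T67S, -3.70 in I68N, -3.78 in P66T/R69K), PIGR (-3.34 in T67S, -1.52 in I68N, -1.46 in P66T/R69K) and KRT7 (-0.45 in T67S, -0.43 in I68N, -0.43 in P66T/R69K), and those higher in all 3 included FABP6 (1.18 in T67S, 1.04 in I68N, 1.09 in P66T/R69K) and CEP15 (1.25 in T67S, 1.02 in I68N, 0.92 in P66T/R69K), examples picked after the values were seen. The 3 ctrl arrays cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

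These overlaps depended on single arrays. Calls in the same direction for T67S and I68N were 75 to 160 without 1 array other than ctrl 1, ctrl 2, P66T/R69K 1 or P66T/R69K 2 and 2706 without ctrl 2, for T67S and P66T/R69K 31 to 58 without 1 array other than ctrl 1, ctrl 2 or T67S 3 and 1243 without ctrl 2, and for I68N and P66T/R69K 51 to 72 without any of I68N 1, I68N 2, I68N 3, P66T/R69K 1, P66T/R69K 2 or P66T/R69K 3 and 1247 without ctrl 2. Genes higher in all 3 were 13 to 23 without 1 array other than ctrl 1 or ctrl 2 and 738 without ctrl 2. Genes lower in all 3 were 5 to 10 without 1 array other than ctrl 1, ctrl 2 or T67S 3 and 34 without ctrl 1 and 186 without ctrl 2.

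A single test over the 4 groups, limma's F test, called 3325 genes. The smallest p-values belonged to SLCO1B3 (adjusted p = 5.98e-08), with a log2 signal of 8.85 ± 0.05 in ctrl, 9.79 ± 0.10 in T67S, 6.60 ± 0.33 in I68N and 5.56 ± 0.17 in P66T/R69K (SD, n = 3), and to the matrix proteoglycan biglycan, BGN (adjusted p = 5.98e-08), at 9.10 ± 0.02, 8.22 ± 0.12, 10.43 ± 0.08 and 8.81 ± 0.05. Also among the 10 were ZMAT1 (2.28e-07), MGA (4.72e-07), AUTS2 (4.95e-07), TMEM252 (2.5e-06), PRSS3P2 (2.5e-06), IL33 (2.67e-06), CTSE (2.67e-06) and SLC14A1 (2.67e-06), given with their adjusted p. On leaving out single arrays the count was 2124 without P66T/R69K 3, 2131 without P66T/R69K 2, 2187 without I68N 2, 2195 without I68N 1 and 7078 without ctrl 2.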

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

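The tests weighed here were chosen only after the result was seen. Genes called against ctrl in opposite directions in 2 mutants, and called between these mutants too, numbered 39 for T67S and I68N, 89 for T67S and P66T/R69K and 39 for I68N and P66T/R69K. Lists met the same conditions. Between T67S and P66T/R69K they were the interferon response (median log2 fold change -1.25), MHC class I (-0.80) and ribosomal proteins (0.33). Between I68N and P66T/R69K they were the interferon response (-1.10), MHC class I (-0.63), ribosomal proteins (0.25), glycolysis (0.31) and xenobiotic metabolism (0.23). With an estimated correlation none of these list differences passed. Outside the genes analysed, 169 probe sets with several symbols and 530 with no annotation passed the F test. Groups of 3 were not tested for single deviating arrays.

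The interferon response list was called lower in T67S and I68N and higher in P66T/R69K than in ctrl, with 4, 1 and 7 of 29 genes passing and adjusted p = 0.647, 0.869 and 0.408 with an estimated correlation. A single aberrant ctrl array is argued against as the whole cause for T67S and P66T/R69K. Whichever ctrl array was left out, the list median was at most -0.33 in T67S and at least 0.57 in P66T/R69K, and the mean list score differed from ctrl by more than the larger SD of the arrays. For I68N it stays open, with a median of -0.0945 without ctrl 2 and -0.14 without I68N 3 and scores of -0.06, -0.13 and -0.83 against -0.23, 0.45 and -0.07 in ctrl. Immune cells in the tumours may differ between groups, and this stays open. The lower of the medians of the myeloid and lymphocyte lists was -0.000576 and the other 0.00272, but their median levels of 6.17 and 6.33, against 7.68 over all genes, are low, and mouse cells would be read only by cross-hybridisation. A mutant effect, a difference between the stable lines and handling by group cannot be told apart, since each coincides with the groups.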

How the results depend on the processing

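Array weights were chosen only after the spread of the ctrl arrays was seen. Of 463 values of named genes none reversed under any alternative run. The same side of the threshold was kept by 429 with quantile normalization, 460 with all rows, 455 with a variance trend, 408 with the replicate block and 376 with array weights, by 409 of 416 without dim genes, 291 of 405 in 2-group fits and 4845 of 5556 without 1 array. Of 288 values past the threshold, 147 stayed past it under every alternative run. Of 81 list calls, 2 passed with an estimated correlation and 61 after quantile normalization. The median of 1, epithelial junctions in T67S against P66T/R69K, reversed to -0.0226 after quantile normalization, and the cause was not tested. Counts of genes against ctrl were, for T67S, I68N, P66T/R69K and the mutants' mean, 547, 544, 439 and 101 with the replicate block, though replicate numbers do not pair these samples (correlations -0.403 to 0.202 in 18 same-numbered pairs, and 0 of 12 arrays closest to their own number), and 360, 473, 316 and 30 with array weights, and 11, 191 and 150 in 2-group fits for the first 3. With array weights T67S against I68N gave 1991, T67S against P66T/R69K 4034 and I68N against P66T/R69K 3933 genes, and in 2-group fits they gave 1785, 3842 and 3961. A spread pooled with the wider ctrl arrays, or an error held by fewer samples, is part of how these fits are built, and beyond that the cause was not tested. Lists called with an estimated correlation were 1 for T67S, 0 for I68N and 0 for P66T/R69K against ctrl by camera, 0, 0 and 0 between mutants and 1 for the mean. The lowest adjusted p where none was called was 0.0669, 0.122, 0.765, 0.481 and 0.394, and for every called list the estimated correlation was above the preset one. After quantile normalization 7 lists were called for T67S against I68N and 4 for the mean, and the cause was not tested.

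Leaving out each array in turn gave, in the same order of the 7 comparisons, 272 to 4752, 267 to 4184, 332 to 2673, 573 to 1722, 1626 to 4238, 1032 to 3375 and 72 to 4099 genes and 10 to 16, 6 to 10, 12 to 16, 8 to 12, 10 to 14, 10 to 15 and 4 to 15 lists, 2124 to 7078 genes in the F test, 75 to 2706, 31 to 1243 and 51 to 1247 shared calls per pair of mutants, 13 to 738 genes higher and 5 to 186 lower in all 3. The highest gene counts came without ctrl 2. CSNK1D differed from ctrl by -0.08 to -0.04, -0.04 to 0.00 and 0.05 to 0.10. Dim genes near the background limit what the arrays can show, and 1 named call was lost without them.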

Other observations

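Tests chosen only after the result was seen were the correlation and covariance of distant neighbours, the ctrl arrays left out and the covariance for shared controls. Whole stretches of 50 neighbouring expressed genes were shifted (median log2 difference from the ctrl mean over the genes, mean ± SD of 3 arrays). From FBXO25 to EXTL3 T67S stood at 0.42 ± 0.06, I68N at -0.21 ± 0.02 and P66T/R69K at -0.28 ± 0.04. From BAGE5 to FOXO1 they stood at -0.14 ± 0.02, 0.12 ± 0.01 and -0.26 ± 0.01, and from NET1 to RAB18 at 0.37 ± 0.05, 0.32 ± 0.03 and 0.26 ± 0.08. Of 819 overlapping stretches, 27, 28, 63, 51, 76 and 47 lay beyond the highest shuffled value in T67S, I68N and P66T/R69K against ctrl, T67S against I68N, T67S against P66T/R69K and I68N against P66T/R69K, and they held 4.67, 5.65, 10.5, 8.69, 10.9 and 6.85% of the placed genes and 22.6, 19.9, 29, 42.4, 27.3 and 20% of those called, a share that their choice by the change itself raises.

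Copy number or other regional differences between the stable lines are a candidate explanation. Fold changes of T67S against P66T/R69K correlated at 0.118 between expressed genes 20 to 40 genes apart, against at most 0.00774 in 1000 shuffled orders. Signal shared by neighbours of 1 family is argued against as the whole cause, since adjacent genes with unlike symbols correlated at 0.184 (shuffled at most 0.0303) and the distant ones remained correlated. Random array to array differences are argued against between mutants by the covariance, 0.00129 at most between 2 arrays of a mutant group and at least 0.00577 between mutant groups. Against ctrl they stay open, since ctrl 1 and ctrl 2 reached 0.00561 and T67S and I68N against ctrl 0.00467 and 0.00487. As a correlation the bounds between mutants were 0.0717 and 0.0789, too close to exclude array or RNA quality that follows regions, and handling by group cannot be told apart from the groups.

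For the genes lower in all 3 mutants as a set, 1 aberrant ctrl array is not excluded. It is argued against for DUOX2, whose log2 fold change was -3.07 or lower in each mutant whichever ctrl array was left out (adjusted p at most 0.000188). All 3 ctrl arrays lay above all 9 mutant arrays in 20 of 20 genes, which their selection largely fixes. Among genes called lower in all 3 without a ctrl array, that array lay above all mutant arrays in 14 of 34 for ctrl 1, 38 of 186 for ctrl 2 and 5 of 5 for ctrl 3, at the lowest 20.4%, where chance gives 10%. Chance values of the shared ctrl arrays may also contribute, because the observed covariance of fold changes exceeded the simulated one in 1 pair and lay below it in the others, by -0.00637 at the lowest, and 20 shared genes lie within the simulated range. An effect common to the mutants was not separated from these.

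Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave as many genes. In the same order it gave 982, 915, 759, 1008, 2677 and 2039, against 4, 0, 0, 0, 0 and 0 at most elsewhere. For lists 2, 7, 1, 3, 3 and 4 splits gave as many. The real ones gave 13, 9, 14, 11, 12 and 11 lists, against 13, 15, 13, 16, 15 and 13 at most elsewhere. Of 100 drawn splits of the 12 arrays, 1, the real one, gave as many genes in the F test (3325 against 569). That lowest possible share argues against purely chance labels. These splits, like those of 6 arrays, mix groups that differ, which widens their spread. For the mutants' mean 3 gave as many genes (246 against 1290), and chance is not excluded. The higher count in another split may point to a structure of the samples, which was not tested, and the count was 30 with array weights and 72 without ctrl 3. For its lists 46 splits gave as many (11 against 17), so here too chance is not excluded.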
